A study of Mus musculus with 27 samples.

How the data were processed

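Colonic RNA was profiled by poly(A) RNA sequencing in 27 libraries from 14 mice of mixed background. Per the labels, mice of the deficient group carried Villin1-Cre, a recombinase expressed in the intestinal epithelium, together with loxP-flanked alleles of both Foxa1 and Foxa2. There were 7 proximal control, 7 proximal deficient, 6 distal control and 7 distal deficient libraries, and 13 mice gave both segments. Groups, replicate numbers, sex and age were taken from the labels, and each replicate was a separate mouse. Per the labels' protocols, RNA came from short pieces of whole colonic tissue, so epithelium, muscle, immune and stromal cells were measured together.

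Per the submitters' processing notes, reads were handled with bcl2fastq 2.20.0.422, cutadapt 2.5 and kallisto 0.46.2 on the GRCm38 (mm10) build, and edgeR was also named, without a version. The authors deposited estimated counts per transcript for each library, with TPM (length-scaled transcript abundance) and effective lengths beside them. The TPM deposited by the authors were not used for any result. The authors also deposited a matrix of log2 CPM per gene for each segment, whose normalization is not given in the sources used here. The single-end or paired-end setting is likewise not given in the sources used here. Transcript length minus effective length was 249 bases in every distal library and between 214.56 and 245.61 bases in the proximal libraries, so fragment length was handled differently in the quantification of the segments.

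Transcripts were joined to genes of the GENCODE M21 annotation by identifier, with the version number left out. Of 119414 transcripts, 116728 matched, and the 2686 others held between 0.9% and 1.27% of the counts of a library and were left out. Expected counts were summed per gene over 35975 genes and rounded to whole numbers. Total estimated counts ranged from 18472867 to 56744113 per library with a median of 40556273, from 35961132 to 54196293 in proximal and over the whole of that range in distal libraries. The 10 most abundant genes took between 8.34% and 12.2% of a library. Reads of near-identical gene copies were divided by kallisto's model, so values of members of multigene families are uncertain.

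Each comparison was fitted with the edgeR 4.0.16 quasi-likelihood test (glmQLFit and glmQLFTest, R 4.3.3) after filterByExpr and TMM normalization. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Deficient and control mice were compared within each segment without covariates. The difference of the genotype effect between segments was fitted over 26 libraries of 13 mice with mouse as a block. Segments were compared within the 6 control mice and within the 7 deficient mice, again with mouse as a block. Levels are CPM, counts divided by the TMM-scaled library size, given as mean and SD over libraries, and log2 fold changes are given with their standard error (SE). Levels of Y-linked genes, defensins and the summed small-intestinal list were scaled with no filter on low counts. So were the Foxa1 and Foxa2 levels set beside distal controls without Cre, which differ slightly from those given elsewhere. Adjusted p-values of genes are from this test throughout.

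Gene lists for cell types and pathways, 39 in number, were written before the data were examined, and 38 of them had at least 5 tested genes. The gastric epithelium list had 3 tested genes in proximal colon and 2 in distal colon, of which 0 passed (1 distal gene when adjusted over the list alone), and it was not tested as a list. Lists were tested with camera (limma 3.58.1) with an inter-gene correlation preset at 0.01, then with an estimated correlation and with fry. Counts of list members "adjusted over the list alone" use the same gene p-values with adjustment over that list.

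Also fixed before the data were examined was the rule for named genes. It took Foxa1 and Foxa2, the 8 highest and 8 lowest log2 fold changes past the threshold with at least 5 mean CPM in the higher group (per genotype comparison and for the segments of control mice), the 8 smallest p for the difference between segments, and up to 4 members per list past the threshold. Unnamed genes, immunoglobulin and T cell receptor segments and sex-determining transcripts were left out of the ranking. To shorten the text, only the 2 members of smallest p were kept for each list past the threshold, and for the segment comparison only those of the 8 lists of smallest p. That shortening was chosen after the values were seen. Some genes that the rule takes are not reported here.

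The procedures were tested on simulated counts with known changes. Simulated 2-fold changes were recovered for 79% of genes in the proximal and 65% in the distal genotype comparison, for 47% in the difference between segments, and for 85% and 79% in the segment comparisons of control and deficient mice. Simulated 4-fold changes were recovered for 93%, 94%, 84%, 100% and 99% in the same order.

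Alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts or a stricter filter of 1 CPM, a transcript-length offset, the deposited matrices, subsets by sex, age or Cre, age and sex as covariates, the replicate number as a block, no mouse block, and each mouse left out. Added after the data were examined were mice male by both label and Y-linked transcripts, the smooth muscle level as a covariate, control mice without Cre for the difference between segments and for the control segment comparison, and genes of at least 500 bases. The overlap of called genes between segments was set beside lists of the same sizes, ranked by limma's moderated statistic, from residuals of the same mice with genotypes reassigned and from disjoint sets of mice, 100 draws each. Libraries of a group were compared pairwise for duplication, and the lowest chi-square per degree of freedom between any pair was 30, far above sampling noise. Proximal and distal libraries with the same number came from the same animal per the labels. Their deviations from the group means correlated with a median of 0.26 (range -0.09 to 0.49), and 10 of the 13 pairs correlated best with their own partner.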

Results

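The transcriptome of adult mouse colon was measured in control mice and in mice lacking the forkhead transcription factors Foxa1 and Foxa2 in the intestinal epithelium. Proximal colon was sampled from 7 control and 7 deficient mice, and distal colon from 6 control and 7 deficient mice. All control mice were labelled male, and 2 of the deficient mice were labelled female. Control mice were 9 to 18 months old and deficient mice 9 to 13 months old. Of the control mice, 5 carried no Cre and 2 carried Villin1-Cre with at least 1 wild-type Foxa2 allele. Libraries held 18472867 to 56744113 estimated counts.

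The targeted genes were examined first in every library. Foxa1 (ENSMUSG00000035451.7, chromosome 12, 57540628 to 57546916, minus strand, GRCm38) was at 11 to 15.7 CPM in the 7 proximal deficient libraries and at 55.3 to 75 CPM in 6 of the 7 proximal control libraries. The remaining library, labelled control replicate 6, was at 15 CPM. Its label gives Villin1-Cre with both Foxa1 alleles loxP-flanked and 1 wild-type Foxa2 allele, and it kept Foxa2 at 16.9 CPM. Foxa2 (ENSMUSG00000037025.11, chromosome 2, 148042877 to 148046969, minus strand, GRCm38) was at 1.34 to 1.92 CPM in proximal deficient and 6.57 to 16.9 CPM in proximal control libraries. In distal colon Foxa1 was at 6.69 to 9.51 CPM in deficient libraries and at 38.6 to 72.4 CPM in control libraries, except 6.87 CPM in the library labelled control replicate 6. Distal Foxa2 was at 0.298 to 1.24 CPM in deficient and 14.1 to 27.2 CPM in control libraries. Both genes fell in proximal colon (Foxa1 log2 fold change -2.24, SE 0.25, adjusted p = 2.03e-05, and Foxa2 -2.67, SE 0.2, adjusted p = 5.07e-07). Both also fell in distal colon (Foxa1 -2.48, SE 0.36, adjusted p = 0.000716, and Foxa2 -4.49, SE 0.26, adjusted p = 4.51e-07). The distal Foxa1 call was lost with a transcript-length offset (log2 fold change -0.83, adjusted p = 0.0517). Counts were taken over the whole gene, and the exons removed by Cre were not analysed here.

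**Figure D1:**
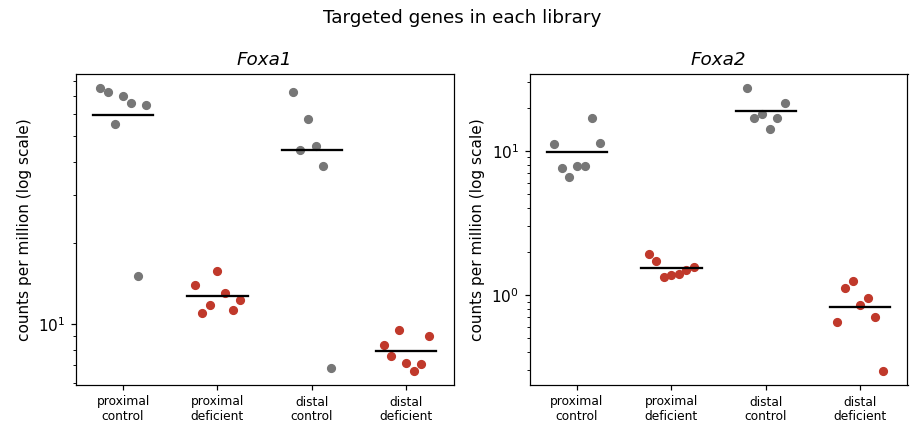
Foxa1 and Foxa2 in CPM (counts scaled to library size) on a log axis, with a point for each library and a line at the mean of each group (7 proximal control, 7 proximal deficient, 6 distal control and 7 distal deficient libraries). In each segment the library labelled control replicate 6 lies among the deficient libraries for Foxa1, at 15 and 6.87 CPM, and among the controls for Foxa2, at 16.9 and 21.5 CPM.

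Sex labels were compared with Y-linked transcripts. The deficient mouse of replicate 3, labelled male, had Ddx3y at 0.0237 CPM in proximal and 0.57 CPM in distal colon. The mice labelled female had 0.0669 and 0.321 CPM in proximal and 0.178 and 0.265 CPM in distal colon, and all other mice labelled male had at least 29.6 CPM.

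The first comparison asked what loss of both factors changed in proximal colon. Of the genes tested, 12 of 20 goblet cell, 13 of 18 mucin glycosylation and 5 of 10 gut hormone genes fell (1, 2 and 2 rose), and 14 of 15 small-intestinal enterocyte genes rose. With an estimated correlation these 4 lists had an adjusted p of 0.204, 0.0922, 0.167 and 0.134. Muc2, the main secreted mucin of the colon, fell from 2720 ± 663 to 970 ± 209 CPM (SD, n = 7 each). Gcg, which encodes proglucagon, fell from 52.1 ± 9.13 to 6.59 ± 1.36 CPM, and the aminopeptidase gene Anpep rose from 9.7 ± 3.87 to 405 ± 211 CPM. Of 16787 genes tested, 1962 were called (927 higher and 1035 lower in deficient mice), 582 of them by at least 2-fold.

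Of the 15 small-intestinal enterocyte genes tested, 14 rose, 0 fell and 1 did not pass (14 rose when adjusted over the list alone), with a median log2 fold change of 3.29. The list passed camera (adjusted p = 1.28e-17, adjusted p = 0.134 with an estimated correlation). Apoa4 and Apoa1, apolipoproteins of lipid-absorbing enterocytes, rose with log2 fold changes of 7.83 (SE 1.11) and 7.18 (SE 1.14), and spread widely, at 88.2 ± 109 and 70.7 ± 96.2 CPM in deficient mice. The ileal bile acid-binding protein gene Fabp6 rose from 5.39 ± 6.19 to 173 ± 198 CPM. Mttp, needed to load lipoproteins with lipid, rose from 5.43 ± 3.13 to 59.8 ± 30.1 CPM, and Fabp1 from 0.512 ± 0.207 to 11.7 ± 17.5 CPM. Outside the list, the cholesterol transporter gene Npc1l1 (log2 fold change 4.49), the phospholipase gene Pla2g4c (5.91) and Olfm4 (4.62) were among the 8 largest increases of ranked genes of at least 5 CPM in the higher group. In the same libraries the Paneth cell defensins Defa24, Defa30 and Defa17 summed to 48.3 CPM in deficient replicate 3 and to at most 2.5 CPM in the other 6 deficient libraries.

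Of 20 goblet cell and mucus genes, 12 fell, 1 rose and 7 did not pass (14 fell and 1 rose when adjusted over the list alone). The list was lower with camera (adjusted p = 3.4e-10, adjusted p = 0.204 with an estimated correlation). Bcas1 fell with Muc2, with a log2 fold change of -1.43 (SE 0.17). Of 18 mucin O-glycosylation genes, 13 fell, 2 rose and 3 did not pass (14 fell and 4 rose when adjusted over the list alone, adjusted p = 3.22e-07, adjusted p = 0.0922 with an estimated correlation). Galnt4, which starts O-glycan chains, fell from 342 ± 18.5 to 175 ± 22.2 CPM, and Gcnt3, which branches them, from 476 ± 60.9 to 229 ± 23.5 CPM.

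Of 10 enteroendocrine hormone genes, 5 fell and 2 rose (6 fell and 2 rose when adjusted over the list alone, adjusted p = 2.79e-05, adjusted p = 0.167 with an estimated correlation). Tph1, the enzyme of gut serotonin synthesis, fell from 26.1 ± 10.2 to 0.727 ± 0.407 CPM, and the neurotensin gene Nts from 63.2 ± 10.0 to 5.27 ± 2.41 CPM. General enteroendocrine cell genes went both ways, with 5 of 19 higher and 6 lower (6 and 6 when adjusted over the list alone, adjusted p = 0.698). Of 13 tuft cell genes, 4 rose, among them Sh2d6 and Alox5 (7 rose when adjusted over the list alone, adjusted p = 4.05e-05, adjusted p = 0.297 with an estimated correlation). Over the enteroendocrine cell list the median log2 fold change was 0.05 and the mean -0.19.

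**Figure D2:**
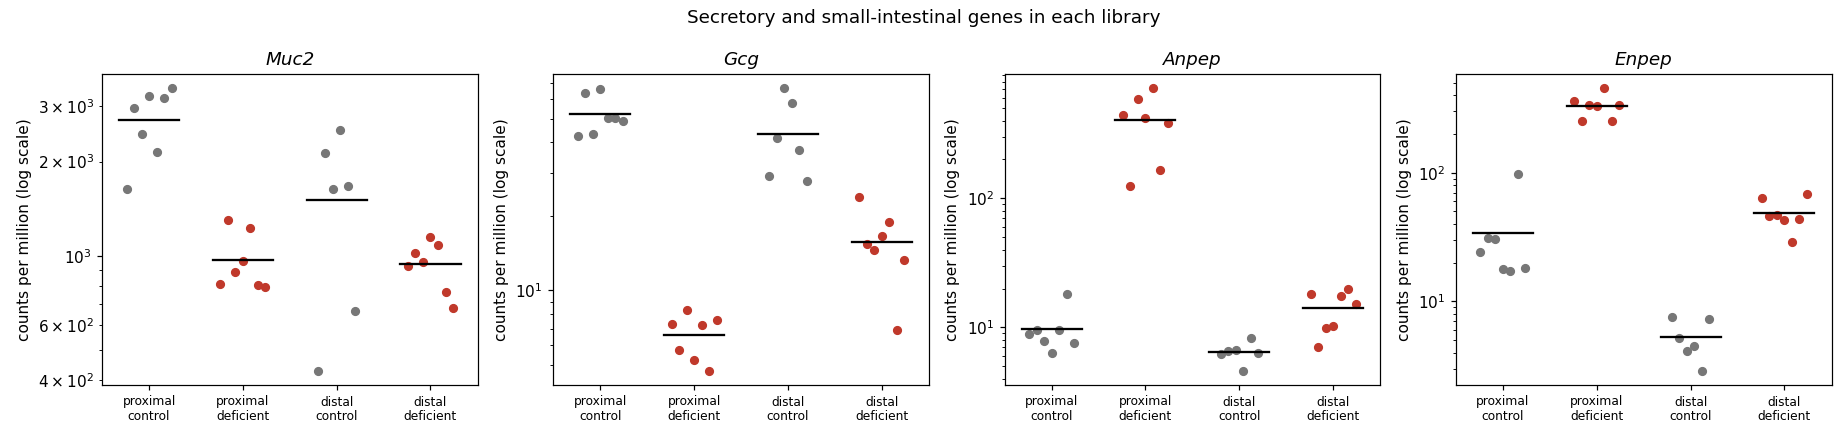
Muc2, Gcg, Anpep and Enpep in CPM (counts scaled to library size) on a log axis, with a point for each library and a line at the mean of each group. Proximal Anpep lay between 124 and 711 CPM in the deficient libraries and between 6.38 and 18.1 CPM in the controls, and proximal Gcg between 4.72 and 8.32 CPM in the deficient and 42.4 and 65.8 CPM in the control libraries.

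Among absorptive and transport genes, changes went in both directions. Of 18 absorptive colonocyte genes, 5 rose and 2 fell (8 and 2 when adjusted over the list alone, adjusted p = 0.00218, adjusted p = 0.539 with an estimated correlation), and the bile acid exporter subunit gene Slc51a rose from 148 ± 49.1 to 368 ± 91.1 CPM. The uroguanylin gene Guca2b also rose, with a log2 fold change of 1.7 (SE 0.23). Of 25 ion and water transport genes, 7 fell and 3 rose (7 and 4 when adjusted over the list alone, adjusted p = 0.0143, adjusted p = 0.297 with an estimated correlation). That list did not pass camera among mice labelled male (adjusted p = 0.0567) or with control mice without Cre only (adjusted p = 0.0708). The carbonic anhydrase gene Car2 fell from 752 ± 246 to 69.7 ± 19.8 CPM and the sodium channel subunit gene Scnn1b from 5.98 ± 0.688 to 1.02 ± 0.385 CPM. Of 23 xenobiotic metabolism genes, 8 fell and 5 rose (10 and 6 when adjusted over the list alone), and the list did not pass (adjusted p = 0.282). Its member Sult1c2 fell with a log2 fold change of -3.88 (SE 0.31). Sycn, Ccn3, Nxpe2, Ak4 and Gna14 completed the 8 largest decreases, with log2 fold changes from -5.08 to -3.61.

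Fatty acid oxidation genes rose for 9 of 17 members, with 0 lower (11 higher and 1 lower when adjusted over the list alone, adjusted p = 1.93e-05, adjusted p = 0.297 with an estimated correlation). Pdk4, which restrains glucose oxidation, rose from 68.4 ± 25.4 to 313 ± 74.9 CPM, and the carnitine carrier gene Slc25a20 from 272 ± 31.2 to 384 ± 50.4 CPM. Of 19 cholesterol synthesis genes, 7 rose and 0 fell (9 rose when adjusted over the list alone, adjusted p = 7.68e-06, adjusted p = 0.442 with an estimated correlation), including Sqle and Idi1 at log2 fold changes of 0.87 and 0.64. Of 16 crypt stem cell and Wnt target genes, 5 fell and 1 rose (6 and 1 when adjusted over the list alone, adjusted p = 0.00445, adjusted p = 0.297 with an estimated correlation), with Rgmb at -0.7 (SE 0.08) and Ephb3 at -1.08 (SE 0.14). Of 20 unfolded protein response genes, 2 fell, Herpud1 and Asns (2 when adjusted over the list alone, adjusted p = 0.0405, adjusted p = 0.442 with an estimated correlation). Among 13 mitochondrially encoded genes 1 fell, mt-Nd4 at -0.32 (1 when adjusted over the list alone, adjusted p = 0.000533, adjusted p = 0.297 with an estimated correlation).

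Immune and stromal markers were measured beside the epithelium. Of 8 mast cell genes, 6 rose and 1 fell (6 and 1 when adjusted over the list alone, adjusted p = 2.79e-05, adjusted p = 0.204 with an estimated correlation), Mcpt4 rising from 0.06 ± 0.0682 to 1.39 ± 0.681 CPM. The member that fell was Kit, from 57.1 ± 10.4 to 28.7 ± 6.23 CPM, which is also on the Paneth and deep crypt secretory cell list, where 2 of 7 genes fell (1 rose and 2 fell when adjusted over the list alone, adjusted p = 0.289). Of 17 macrophage and monocyte genes 2 rose, Mertk and Itgam (2 when adjusted over the list alone, adjusted p = 0.00774, adjusted p = 0.61 with an estimated correlation), and of 14 fibroblast genes 2 rose, Pdgfra and Grem1 (2 when adjusted over the list alone, adjusted p = 0.026, adjusted p = 0.644 with an estimated correlation). Of 6 neutrophil genes 1 rose, Ly6g, a member of a gene family of close copies, at 2.06 ± 1.23 CPM (3 when adjusted over the list alone, adjusted p = 0.0405, adjusted p = 0.204 with an estimated correlation). B cell genes had a median log2 fold change of -1.7, with 0 of 12 past the threshold (6 fell when adjusted over the list alone, adjusted p = 0.00218, adjusted p = 0.61 with an estimated correlation).

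The other proximal lists did not pass camera. Of interferon-stimulated genes 1 of 23 rose, of antimicrobial defence genes 2 of 12 rose and 2 fell, and of inflammatory cytokine and chemokine genes 1 of 18 rose and 1 fell. Of type 2 immunity genes 2 of 11 rose and 1 fell. Of T and NK cell genes 1 of 18 rose and 1 fell, of plasma cell genes 1 of 11 rose, and of proliferation genes 1 of 23 fell. Of epithelial junction genes 2 of 21 rose and 2 fell, of epithelial injury and repair genes 4 of 17 rose and 1 fell, and of gut endoderm transcription factors 1 of 15 rose and 2 fell. Of immediate early and heat shock genes 3 of 14 rose, of adipocyte genes 1 of 9 fell, and of anterior Hox genes 1 of 14 fell. The MHC class II presentation, smooth muscle, enteric neuron and glia, endothelial and posterior Hox lists had 0 members past the threshold. When adjusted over the list alone, 3 antimicrobial genes rose and 5 fell, 6 injury and repair genes rose and 1 fell, 4 junction genes rose and 2 fell, 3 type 2 immunity genes rose and 1 fell, and 0 anterior Hox genes passed. None of the 17 lists past camera in proximal colon stayed past it with an estimated correlation. With fry the small-intestinal enterocyte, goblet cell, mucin O-glycosylation and hormone lists had an adjusted p of 2.68e-05, 0.000525, 3.4e-06 and 3.4e-06. The macrophage and monocyte, fibroblast and B cell lists did not pass fry (adjusted p = 0.15, adjusted p = 0.177 and adjusted p = 0.169).

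Of the 44 genes named here besides Foxa1 and Foxa2, 43 lay to the same side of the control mean in all 7 proximal deficient libraries, and Olfm4 in 6. The genes were called in these same libraries, so this describes them and is no separate support. Under at least 1 alternative Olfm4, Alox5, Idi1, Pdgfra, Grem1, Itgam, mt-Nd4 and Ly6g lost their calls, at adjusted p values from 0.0502 to 0.226. Idi1 lost it without control replicate 1 or deficient replicate 3 (adjusted p = 0.0516 and adjusted p = 0.0507), and Grem1 without control replicate 4 or deficient replicate 7 (adjusted p = 0.0507 and adjusted p = 0.0531). Itgam lost it without control replicate 1, 3, 4 or 7 or deficient replicate 1, 2, 3, 6 or 7 (adjusted p from 0.0514 to 0.0802), and Ly6g without control replicate 1, 2, 3, 4, 5 or 7 or deficient replicate 3 or 6 (adjusted p from 0.0523 to 0.0644).

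In distal colon 6 of 26 ion transport, 4 of 20 goblet cell and 5 of 18 mucin glycosylation genes fell (0, 0 and 1 rose), with an adjusted p of 0.309, 0.309 and 0.313 with an estimated correlation. Of enteroendocrine cell genes 10 of 17 rose, of small-intestinal enterocyte genes 6 of 13 and of inflammatory genes 6 of 20, with an adjusted p of 0.309, 0.309 and 0.418 with an estimated correlation. The hormone gene Insl5 fell from 46.2 ± 9.45 CPM (SD, n = 6) to 0.355 ± 0.174 CPM (SD, n = 7). The water channel gene Aqp4 fell from 406 ± 160 to 14.2 ± 5.64 CPM, and Lcn2, which encodes the antibacterial protein lipocalin 2, rose from 4.55 ± 2.2 to 51.7 ± 37.1 CPM. Of 16041 genes tested, 973 were called (433 higher and 540 lower), 501 of them by at least 2-fold.

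Of 17 enteroendocrine cell genes in distal colon, 10 rose and 0 fell (11 and 2 when adjusted over the list alone, adjusted p = 2.25e-06, adjusted p = 0.309 with an estimated correlation). The transcription factor genes Pax6 and Rfx6, which act in endocrine lineages, rose from 1.49 ± 0.27 to 5.0 ± 0.675 CPM and from 0.529 ± 0.226 to 3.27 ± 0.864 CPM. Hormone genes went both ways, with 3 of 9 lower and 2 higher (4 and 2 when adjusted over the list alone, adjusted p = 0.045, adjusted p = 0.313 with an estimated correlation). The hormone list did not pass camera with control mice without Cre only (adjusted p = 0.1) or in mice of 9 to 13 months (adjusted p = 0.0747). Besides Insl5, Tph1 fell with a log2 fold change of -5.3 (SE 0.36). Of 20 goblet cell and mucus genes 4 fell (9 when adjusted over the list alone, adjusted p = 2.25e-06, adjusted p = 0.309 with an estimated correlation), among them Capn9 (-1.29, SE 0.16) and Bcas1 (-1.04, SE 0.19). Of 18 mucin O-glycosylation genes 5 fell and 1 rose (9 and 2 when adjusted over the list alone, adjusted p = 0.00228, adjusted p = 0.313 with an estimated correlation). The fucosyltransferase gene Fut2 fell from 337 ± 49.0 to 174 ± 33.2 CPM, and Galnt4 fell as in proximal colon.

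Of 26 ion and water transport genes 6 fell and 0 rose (6 and 1 when adjusted over the list alone, adjusted p = 0.000845, adjusted p = 0.309 with an estimated correlation), the potassium channel subunit gene Kcne3 from 87.9 ± 24.9 to 23.5 ± 4.14 CPM. Of 22 xenobiotic metabolism genes 5 fell and 1 rose (6 and 1 when adjusted over the list alone, adjusted p = 0.000154, adjusted p = 0.309 with an estimated correlation), including Gstm1 and Sult1c2. Of 13 small-intestinal enterocyte genes 6 rose and 0 fell (7 and 1 when adjusted over the list alone, adjusted p = 0.000154, adjusted p = 0.309 with an estimated correlation), Enpep from 5.27 ± 1.85 to 48.8 ± 13.3 CPM and Mttp from 3.7 ± 0.915 to 11.6 ± 3.74 CPM. Of 18 absorptive colonocyte genes 2 fell and 1 rose (3 and 1 when adjusted over the list alone, adjusted p = 0.0268, adjusted p = 0.688 with an estimated correlation), with Car1 from 641 ± 381 to 53.9 ± 31.1 CPM and Guca2b up by a log2 fold change of 1.89. Among ranked genes of at least 5 CPM in the higher group, the largest increases were Serpinb11, Klk15, Slc6a19, Creb3l3, Ggt1, Krt36 and Slc30a2 beside Lcn2, with log2 fold changes from 6.48 to 3.45. The largest decreases were St8sia5 (-7.84), Vsig2 (-4.43), Nat8f3 (-4.15) and those named above, and St8sia5 varied widely among controls, at 32.2 ± 40.9 CPM.

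Immune and epithelial injury lists were also tested in distal colon. Of 20 inflammatory cytokine and chemokine genes 6 rose and 0 fell (10 when adjusted over the list alone, adjusted p = 0.000845, adjusted p = 0.418 with an estimated correlation), Il1b from 4.59 ± 1.59 to 18.9 ± 10.2 CPM and Ccl20 from 20.1 ± 7.01 to 89.0 ± 58.9 CPM. Of 7 neutrophil genes 4 rose (5 when adjusted over the list alone, adjusted p = 0.00036, adjusted p = 0.313 with an estimated correlation), with Mmp9 from 0.993 ± 0.375 to 6.29 ± 4.32 CPM and S100a9 at a log2 fold change of 2.52. Of 8 mast cell genes 2 rose, Mcpt1 and Mcpt2 (5 when adjusted over the list alone, adjusted p = 0.00306, adjusted p = 0.309 with an estimated correlation). Of 16 epithelial injury and repair genes 2 rose, Ereg and Mmp10 (4 when adjusted over the list alone, adjusted p = 0.0232, adjusted p = 0.646 with an estimated correlation). Single members rose among interferon-stimulated genes (Ifit2, 1 of 23, adjusted p = 0.000848), macrophage and monocyte genes (Itgam, 1 of 17, adjusted p = 0.00783) and cholesterol synthesis genes (Mvd, 1 of 19, adjusted p = 0.0112), and these lists had an adjusted p of 0.646, 0.681 and 0.718 with an estimated correlation.

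With 0 members past the threshold, the distal mitochondrially encoded (adjusted p = 2.52e-05), enteric neuron and glia (adjusted p = 0.000873), smooth muscle (adjusted p = 0.00107) and adipocyte (adjusted p = 0.00559) lists were lower, and the proliferation (adjusted p = 0.0157) and T and NK cell (adjusted p = 0.04) lists were higher. With an estimated correlation these 6 lists had an adjusted p of 0.313, 0.646, 0.646, 0.646, 0.718 and 0.718. Proliferation turned to lower among controls without Cre (adjusted p = 0.896). The smooth muscle genes had a median log2 fold change of -0.63 in distal and 0.19 in proximal colon. Below the list threshold, 3 of 14 antimicrobial defence genes rose (5 rose and 2 fell when adjusted over the list alone, adjusted p = 0.134), Lcn2 among them, and 3 of 8 Paneth and deep crypt secretory cell genes fell and 1 rose (3 and 2 when adjusted over the list alone, adjusted p = 0.134). None of the 21 lists past camera in distal colon stayed past it with an estimated correlation.

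Of the 38 genes named for distal colon besides Foxa1 and Foxa2, 34 lay to the same side of the control mean in all 7 deficient libraries, and Klk15, Mvd, Ccl20 and S100a9 in 6. These genes too were called in the same libraries, so this is no separate support. The count of 973 genes became 569 among mice male by label and Y-linked transcripts, 645 with labelled sex as a covariate and 1504 with the DESeq2 Wald test. Klk15, Mvd, Il1b, Ccl20, Ifit2, Itgam and S100a9 lost their calls under at least 1 alternative, at adjusted p values from 0.0506 to 0.204. Mvd lost it without control replicate 2, 4, 5 or 6 or deficient replicate 3, 6 or 7 (adjusted p from 0.0527 to 0.0743) and S100a9 without control replicate 1, 3, 4 or 5 (adjusted p from 0.0506 to 0.0573).

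The next comparison asked which genotype effects differed between the segments of the same mice. The effect in distal colon was more negative for 3 of 15 small-intestinal enterocyte genes and more positive for 5 of 19 enteroendocrine cell genes, with an adjusted p of 0.359 for each list with an estimated correlation. Anpep had the smallest p, with 9.28 ± 3.8 CPM in control and 368 ± 190 CPM in deficient proximal colon against 7.07 ± 1.24 and 15.2 ± 5.37 CPM in distal colon (SD, n = 6 controls and 7 deficient mice). Of 17595 genes tested, 178 had a different effect, 76 with a more positive and 102 with a more negative effect in distal colon.

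The retinol-binding protein gene Rbp4 rose in distal colon, from 8.81 ± 1.83 to 37.0 ± 10.4 CPM, and was 9.28 ± 1.86 and 6.89 ± 1.99 CPM in proximal colon, a difference of 2.51 (SE 0.24). Dync1i1 and Map2, known from neurons, had differences of 1.8 and 1.72, and Fmo4 and Olfr165 of -2.23 and -3.82. Car1 fell more in distal colon (-3.1, SE 0.4), where its control level was 700 ± 418 CPM against 15600 ± 2650 CPM in proximal colon. The effect on Foxa2 differed as well (-1.93, SE 0.29, adjusted p = 0.0046), and that on Foxa1 did not pass (-0.14, SE 0.2, adjusted p = 0.83).

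Of 15 small-intestinal enterocyte genes 3 had a more negative effect in distal colon (8 when adjusted over the list alone, adjusted p = 2.32e-10, adjusted p = 0.359 with an estimated correlation). Of 19 enteroendocrine cell genes 5 had a more positive effect (11 and 1 more negative when adjusted over the list alone, adjusted p = 1.47e-08, adjusted p = 0.359 with an estimated correlation), Chga by 1.91 and Scg3 by 1.33. Of 11 hormone genes 3 had a more positive effect (4 when adjusted over the list alone, adjusted p = 0.0477, adjusted p = 0.548 with an estimated correlation), among them Cck by 2.6 and Gcg by 1.55. Inflammatory cytokine and chemokine genes had a more positive effect for 1 of 24, Ccl3 (5 when adjusted over the list alone, adjusted p = 4.27e-06, adjusted p = 0.455 with an estimated correlation). Ccl3 was at 0.214 to 0.513 CPM on average in the groups. Of 24 xenobiotic metabolism genes Ephx2 had a more negative and Sult1a1 a more positive effect (3 more negative and 1 more positive when adjusted over the list alone, adjusted p = 0.011, adjusted p = 0.548 with an estimated correlation). Smooth muscle genes had a median difference of -0.86 with 0 of 13 past the threshold (10 when adjusted over the list alone, adjusted p = 6.1e-07, adjusted p = 0.548 with an estimated correlation), and B cell genes of 1.62 with 0 of 12 (8 when adjusted over the list alone, adjusted p = 3.11e-07, adjusted p = 0.548 with an estimated correlation). Of 18 absorptive colonocyte genes Car1 had a more negative effect (3 when adjusted over the list alone, adjusted p = 4.27e-06, adjusted p = 0.548 with an estimated correlation). Goblet cell and mucus genes had a median difference of 0.3 and a mean of -0.02, with 0 of 20 past the threshold (5 more positive and 1 more negative when adjusted over the list alone, adjusted p = 0.0123, adjusted p = 0.548 with an estimated correlation). Also with 0 members past the threshold, the enteric neuron and glia, fatty acid oxidation, fibroblast and adipocyte lists were more negative, and the proliferation, T and NK cell, crypt stem cell and interferon-stimulated lists more positive, at adjusted p values from 0.000432 to 0.0419, and from 0.548 to 0.665 with an estimated correlation. None of the 17 lists past camera for this difference stayed past it with an estimated correlation.

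For each gene named here besides Foxa1 and Foxa2, the distal to proximal difference lay to the same side of the control mean in 7 of 7 deficient mice, as it did for Foxa2. Since the genes were called in these mice, this is no separate support. The count of 178 became 529 with the DESeq2 Wald test, 70 among mice male by label and Y-linked transcripts, 102 without control replicate 2 and 110 without deficient replicate 3. Car1 lost its call with the DESeq2 Wald test (adjusted p = 0.138), Ephx2 among mice male by label and Y-linked transcripts (adjusted p = 0.0795). Sult1a1 lost it without control replicate 2 or deficient replicate 3 (adjusted p = 0.0604 and adjusted p = 0.0514), and Ccl3 without any 1 of the mice except control replicate 6 and deficient replicate 4 (adjusted p from 0.0604 to 0.107).

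The log2 fold changes of the segments correlated across the 15574 genes tested in both (Pearson r = 0.5, Spearman rho = 0.34), genes not being independent replicates. Both segments came from the same mice. For differences of mean log2 CPM the r was 0.51, and simulated unchanged groups of those mice gave a median r of 0.25 (0 to 0.49). With no filter on low counts the correlation of the log2 fold changes fell to 0.22 over 25791 genes. For differences of mean log2 CPM over those genes it was 0.41, against a median of 0.16 (0.03 to 0.31) for simulated unchanged groups. The covariance of the effects was 0.1171, against a mean of 0.0174 for simulated unchanged groups. Between disjoint sets of mice, drawn 100 times, the median r was 0.35, with a range of 0.24 to 0.46. Each disjoint set held fewer mice than the full comparison of its segment, which lowers r by noise alone. The lower r therefore does not measure the share due to common mice. Genes higher in both segments numbered 201 and genes lower in both 296. Lists of the same sizes from simulated unchanged groups of the same mice, drawn 100 times, shared a median of 45 (12.5 to 90.1) and 63 (12.9 to 124.1) genes, and independent lists would share 23 and 32.8. Lists of those sizes from disjoint sets of mice, again with fewer mice per segment, shared a median of 146.5 and 220 genes. Genes higher in proximal and lower in distal colon numbered 6 and the reverse 9, inside the range of the simulated unchanged groups (3 to 49.9 and 3 to 39), and independent lists would share 28.6 and 26.4.

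Segments were compared within control mice, where 7231 of 16507 genes differed (3548 higher and 3683 lower in distal colon). Distal colon was marked by the posterior patterning gene Hoxb13, at 251 ± 135 against 0.0188 ± 0.0382 CPM (SD, n = 6 mice). Further distal genes were Mptx1 at 3620 ± 2150 against 0.986 ± 0.619 CPM, the transglutaminase gene Tgm3, the caspase gene Casp14, the calcium channel gene Trpv6, the proton pump gene Atp12a and St8sia5. RPS10-NUDT3 was at 0 counts in all 6 proximal libraries and at 9.17 ± 3.39 CPM in distal colon, and no fold is given. Proximal colon was marked by Osr2 at 103 ± 15.9 against 0.212 ± 0.22 CPM, by Cyp3a25, Cyp3a44, Ugt8a and Slc26a1, and by Slc51a at 137 ± 46.2 against 2.32 ± 1.9 CPM. The mitochondrial gene mt-Atp8, a short transcript, was at 189 ± 22 CPM in proximal and 1.06 ± 0.21 CPM in distal libraries. The genes named for this comparison besides Foxa1 and Foxa2 differed between segments in the same direction in 6 of 6 control mice, the mice in which they were called. Fragment length was handled differently in the quantification of the segments. With a transcript-length offset 6882 genes were called, 6098 of them also called without it. Differences in sequencing or quantification between the segments, fragment-length handling included, are confounded with tissue.

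Of 19 cholesterol synthesis genes 16 were higher in distal colon (16 when adjusted over the list alone, adjusted p = 2.69e-05), Sqle by 1.14. Of 23 proliferation genes 18 were lower (22 when adjusted over the list alone, adjusted p = 0.000317), among them Mcm7 and Mcm5. Of 10 MHC class II presentation genes 9 were higher (9 when adjusted over the list alone, adjusted p = 0.00034), with Ciita and H2-DMb2, and of 12 B cell genes 11 were higher (11 when adjusted over the list alone, adjusted p = 0.00034), with Cr2 and Ms4a1. Cr2, Ms4a1 and H2-DMb2 lost their calls without the mouse block (adjusted p = 0.124, adjusted p = 0.0943 and adjusted p = 0.0642). Of 26 ion and water transport genes 15 were higher and 2 lower (16 and 4 when adjusted over the list alone, adjusted p = 0.000868), Scnn1a by 2.91 (SE 0.17). Of 20 unfolded protein response genes 13 were higher and 2 lower (14 and 2 when adjusted over the list alone, adjusted p = 0.00133), including Pdia6 and Sel1l. Of 21 epithelial junction genes 12 were higher and 2 lower (12 and 2 when adjusted over the list alone, adjusted p = 0.00163), with Cldn8 and Tjp1, and of 23 interferon-stimulated genes 10 were higher (10 when adjusted over the list alone, adjusted p = 0.00163), with Gbp2 and Irf1. Each of these 8 lists had an adjusted p of 0.618 with an estimated correlation, and none of the 19 lists past camera (12 higher and 7 lower) stayed past it. Beside these, some muscle and nerve markers were lower in distal colon, as were 3683 of all 16507 genes tested. Of 13 smooth muscle genes 7 were lower (7 when adjusted over the list alone, median -0.53, adjusted p = 0.0301, adjusted p = 0.619 with an estimated correlation). Of 14 enteric neuron and glia genes 4 were lower (3 when adjusted over the list alone, median -0.38, adjusted p = 0.0257, adjusted p = 0.618 with an estimated correlation). Foxa2 was higher in distal colon of control mice (1.28, SE 0.15, adjusted p = 0.000175) and Foxa1 did not pass (-0.28, SE 0.15, adjusted p = 0.152).

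Distal and proximal colon were also compared within deficient mice. Of 15 small-intestinal enterocyte genes 14 were lower (14 when adjusted over the list alone, adjusted p = 1.81e-06, adjusted p = 0.481 with an estimated correlation), with a median of -3.53, against 6 of 13 lower and 2 higher in control mice (6 and 2 when adjusted over the list alone, adjusted p = 0.074). Of 13 smooth muscle genes 13 were lower, with a median of -1.27 (13 when adjusted over the list alone, adjusted p = 0.000106, adjusted p = 0.493 with an estimated correlation). Of 12 B cell genes 12 were higher, with a median of 2.97, and of 10 MHC class II presentation genes 10 were higher (all when adjusted over the list alone, adjusted p = 5e-06 each, adjusted p = 0.481 with an estimated correlation). None of the 24 lists past camera (13 higher and 11 lower) stayed past it with an estimated correlation. In all, 7445 of 16514 genes differed between segments (3752 higher and 3693 lower in distal colon), and 4774 among mice male by label and Y-linked transcripts. Residual Foxa1 was lower in distal colon in 7 of 7 mice (-0.43, SE 0.13, adjusted p = 0.0203), a call lost with the transcript-length offset (adjusted p = 0.641) and without deficient replicate 4 (adjusted p = 0.0588). Residual Foxa2 did not pass (-0.68, SE 0.26, adjusted p = 0.055), and without deficient replicate 3 it did (adjusted p = 0.0396).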

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

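The tests of Foxa dose, tissue position, small-intestinal tissue, age or sex, the transcript-length offset as a test of fragment length, separate batches and other splits of the samples were chosen after the result was seen, and the test of fragment length over short genes before it. Among the named genes, 22 of 172 groups of libraries held 1 library far from the others, where chance gives about 1 in 20, or 8.6. Of the 22, 12 were in proximal control replicate 6 and 4 in distal control replicate 6.

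In proximal control replicate 6, the log2 CPM lay far from the other controls for Foxa1 (3.91), Anpep (4.18), Fabp6 (4.28), Npc1l1 (1.64), Sycn (-0.2), Nxpe2 (0.94), Sult1c2 (3.24), Gna14 (2.79), Guca2b (5.52), Grem1 (2.14), Car2 (8.08) and Mttp (3.63). Each of these except Grem1 lay toward the deficient group. In distal control replicate 6 the same held for Foxa1 (2.79), Serpinb11 (2.04), Krt36 (2.49) and Slc30a2 (1.4), all toward the deficient group. Proximal control replicate 2 was low in mt-Nd4 (11.67). Among distal deficient libraries, replicate 2 was low in Slc30a2 (0.81), replicate 5 in Insl5 (-2.99) and replicate 4 in Sult1c2 (-2.84), and replicate 4 was high in Mcpt1 (5.39) and Mcpt2 (4.7).

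Of 77 named genes, 9 had a genotype effect that differed between the segments in the test of the difference itself, given as distal minus proximal log2 fold change: Foxa2 (-1.93, adjusted p = 0.0046), Anpep (-4.15, adjusted p = 0.000289), Npc1l1 (-4.13, adjusted p = 0.00517), Gcg (1.55, adjusted p = 0.0054), Car2 (1.92, adjusted p = 0.00433), Krt36 (3.94, adjusted p = 0.0121), St8sia5 (-9.64, adjusted p = 0.00891), Nat8f3 (-4.05, adjusted p = 0.00509) and Car1 (-3.1, adjusted p = 0.00258). In control mice St8sia5 was higher in distal than in proximal colon by a log2 fold change of 12.3. Its proximal effect, and so its difference between segments, therefore rests on very few proximal counts.

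The distal control libraries with Cre, replicates 1 and 6, stood toward the deficient mice, at 0.14 and 0.37 on an axis running from controls without Cre (0) to deficient mice (1) over 860 genes, outside the range of -0.07 to 0.04 of the distal controls without Cre. The axis starts at the mean of the few controls without Cre, from which the libraries with Cre were also measured. Noise in that mean moves them toward the deficient side. Each control without Cre was measured from the mean of the others instead. Tissue taken nearer to the proximal colon is argued against, since both libraries with Cre lay on the distal side of the segment axis, at 0.05 and 0.11, where controls without Cre lay between -0.01 and 0.02. In replicate 1, with 1 wild-type allele of each gene, reduced Foxa dose is argued against too: Foxa1 was at 71.7 CPM and Foxa2 at 27 CPM, above the 38.7 to 57.1 and 14.3 to 17.8 CPM of the distal controls without Cre, and its proximal library lay at 0.06, inside the proximal range of -0.06 to 0.1. In replicate 6, with both Foxa1 alleles loxP-flanked, Foxa1 was at 6.83 CPM and the proximal library lay at 0.41, so reduced Foxa1 remains a candidate explanation there, as a hypothesis. Whether replicate 1 was moved beyond that noise, and by what, stays open. Cre itself was not tested apart from the loxP alleles it acts on.

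Small-intestinal enterocyte genes were higher in proximal colon of deficient mice, and deficient replicate 3 alone had 48.3 CPM of Paneth cell defensins. Small-intestinal tissue in that library alone is argued against as the whole cause, because without it 13 of 15 genes stayed higher, with a median log2 fold change of 3.29. Age or sex is argued against as well, since the median was 3.72 in mice of 9 to 13 months and 3.02 in mice male by label and Y-linked transcripts. Small-intestinal tissue in the segments of all deficient mice is argued against too: in 4 of the 7 deficient libraries the summed defensins Defa24, Defa30 and Defa17, which are abundant in small-intestinal crypts, were at most 0.0536 CPM, against up to 0.108 CPM in controls, while the summed list was at 1740 to 3630 CPM, against 760 to 1460 CPM in controls. A contribution of such tissue stays open in the other 3 libraries, where the defensins lay above every control, as do shed surface cells without crypts, which were not tested, and a change of the colonic epithelium itself with loss of Foxa1 and Foxa2, as a hypothesis. Those 3 libraries were deficient replicates 3, 5 and 7, the mice with the lowest Ddx3y in proximal colon. Mice male by label and Y-linked transcripts leave them out, and the median of 3.02 there argues against such tissue in those 3 libraries as the whole cause.

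Between segments of control mice, 7231 genes differed, and transcript length minus effective length was 249 bases in every distal library and lower in every proximal one. Genes of effective length under 500 bases (957 genes) had a median absolute log2 fold change of 0.56, above the 0.4 to 0.46 of abundance-matched longer genes, so fragment-length handling could account for part of the changes of short genes. Over all genes, 6098 of the 7231 were also called with the transcript-length offset (6882 in all), and 43.7% of longer genes were called against 44.9% of short ones. The offset rescales gene totals and does not redo how kallisto divided reads among transcripts. It therefore cannot decide whether fragment-length handling was the cause over all genes. The short mt-Atp8 had a log2 fold change of -6 with the offset, against -7.48 without it. Without the offset the 13 mitochondrially encoded genes had a median of -0.19, with 4 lower and 0 higher in distal colon. With that offset Hoxb13 kept a log2 fold change of 13.57 and Osr2 of -8.71. Differences between the tissues, which the design names, are a candidate explanation for the longer genes, as a hypothesis: the labels name no batch, although one that followed the segments, as the value of 249 does, could not be told apart from them.

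In 100 splits of the libraries or mice, the real split included, chance was excluded for the count of genes in proximal colon (real 1962, highest other 496, 1 split as large) and in distal colon (real 973, highest other 505, 1 split). For the difference between segments (178 genes), 2 of the 100 splits were as large, the real one included. The other, with control replicates 2, 5 and 6 beside deficient replicates 1, 2 and 6, gave 983 genes and 3 lists. Although 2 of 100 is under the 5% bound used here, chance is not called excluded there, because the other split gave more genes than the real one. That split also gave more genes than the real one with the DESeq2 Wald test (2133 against 529), at a like common dispersion (0.0563 against 0.0557), and the 98 remaining splits gave at most 3 genes. Whether that split reflects a structure among the mice was not tested. For the segments, 1 split is the fewest that can be as large, since the real one is counted. By the 5% bound chance was excluded for the segments of control mice (7231, highest other 0, 1 of 32 splits) and of deficient mice (7445, highest other 0, 1 of 64 splits). It was not excluded for the number of gene lists in proximal colon (17, highest other 24, 15 splits), in distal colon (21, highest other 24, 5 splits) or for the difference between segments (17, highest other 18, 7 splits). Taken list by list, a camera p as small as the real one came in under 5 of the 100 splits for some lists. These were 5 of the 17 proximal, 5 of the 21 distal and 3 of the 17 lists for the difference. In proximal colon it came in 1 split, the real one, for the small-intestinal enterocyte, mucin O-glycosylation and hormone lists. For the proximal B cell list it came in 40 splits and for the distal proliferation list in 58.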

How the results depend on the processing

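The subset male by label and Y-linked transcripts and the smooth muscle covariate were chosen after the data were examined, as were genes of at least 500 bases and controls without Cre for the difference between segments and for the segments of control mice; the other alternatives were fixed before. The cause was not tested for any of the changes that follow. With the DESeq2 Wald test the count of genes was 1504 in distal colon and 529 for the difference between segments. Among mice male by label and Y-linked transcripts, a smaller set of mice, it was 569, 70 and, for the segments of deficient mice, 4774. With labelled sex as a covariate it was 645 in distal colon. Deficient replicate 3, labelled male but low in Y-linked transcripts, counted as male there and among mice labelled male. For the difference between segments, leaving out each mouse gave 102 (without control replicate 2) to 225 (without deficient replicate 2), and 110 without deficient replicate 3. With an estimated correlation, 0 lists passed in proximal colon, in distal colon and for the difference between segments, where camera with the preset correlation gave 17, 21 and 17. With fry the numbers were 16, 10 and 2 in the same order. The correlation of the genotype effects was 0.22 with no filter on low counts and 0.56 among genes of at least 10 mean CPM. The proliferation list in distal colon turned from higher to lower among control mice without Cre, with an adjusted p of 0.896. Besides that list, over proximal colon, distal colon and the difference, 15 camera list calls were lost among control mice without Cre and 8 were gained. Among mice labelled male 8 were lost and 4 gained. Among mice of 9 to 13 months, used within each segment only, 4 were lost and 2 gained. Every other alternative left the counts of genes within 1.5 times. Leaving out each mouse gave 1627 to 2255 genes in proximal and 792 to 1007 in distal colon. Both were highest without control replicate 6, the control low in Foxa1. It gave 5381 to 7311 genes for the segments of control and 5906 to 7370 for those of deficient mice when each mouse was left out. Of the 138 results for named genes, 113 kept their call or lack of one under all alternatives, and 0 changed direction past the threshold. Control and deficient mice of the same replicate number share only a number: their deviations from the group means correlated with a median of 0 in proximal (range -0.16 to 0.27) and 0.03 in distal colon (-0.12 to 0.27), and 1 of 7 and 1 of 6 pairs correlated best with their own number. With the replicate number as a block 1696 genes were called in proximal and 689 in distal colon. Without the mouse block the difference between segments gave 222 genes. In simulated data of the same depth and size, 47% of 2-fold differences of the genotype effect between segments were recovered, so that smaller differences are largely out of reach.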

Other observations

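The gene families described here were grouped by symbol stem after the data were examined, and their tests were chosen after the result was seen. Over 248 families in proximal colon, the apolipoprotein L family (Apol, 3 of 11 genes higher, adjusted p = 0.00989) and the bone morphogenetic protein family (Bmp, 4 of 10 higher, adjusted p = 0.0125) passed camera. Over 239 families in distal colon, 7 passed. Of the lower ones, the Nat symbols had 4 of 11 genes lower (adjusted p = 0.00913), the cytochrome c oxidase symbols (Cox) 1 of 22 (adjusted p = 0.0168), Ndufb 0 of 10 (adjusted p = 0.0306), Atp 1 of 66 lower and 1 higher (adjusted p = 0.0365) and Ndufs 0 of 8 (adjusted p = 0.0432). The Pcdhb and Ifi symbols were higher, with 1 of 13 and 1 of 15 genes past the threshold (adjusted p = 0.0365 each). With an estimated correlation the adjusted p was 0.995 for Apol and Bmp, 0.957 for Nat and 0.989 for the 6 other distal families.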
